A study of Mus musculus with 12 samples.

How the data were processed

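Total RNA from the left atrium of 12 mice was measured by sequencing, after 600 ng of each RNA had been depleted of ribosomal RNA, fragmented for 6 minutes and amplified for 9 cycles, and the libraries were read on a NextSeq 500. The labels also call the molecule poly(A) RNA, which differs from the kit they name. The submitters list STAR 2.5.2b, DESeq2 1.20.0, R 3.5.1 and the mouse genome GRCm38 (mm10) for their processing. The program that assigned reads to genes, the gene annotation and the treatment of strand are not given in the sources used here.

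The deposited values are a signal per gene and library: read counts divided by 1 size factor per library, for 17670 genes in 12 columns, with replicates kept apart. In every column 100% of the values were whole multiples of the column's smallest step, within a tolerance of 0.01 read, so whole reads could be recovered. They totalled 11935100 to 28690100 per library, and 1 read stands for a value of 0.801 to 1.98. Every gene in the table has at least 12 reads over the 12 libraries, so genes with fewer are absent from it. Reads were not deduplicated by molecular identifiers as far as stated, and a statement of reads covers counting error only. The size factors assume that most genes do not change. The median log2 difference over tested genes was 0.00 between deletion and control, but such scaling tends to give this by itself, so it does not test the assumption.

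Genes were kept when their value was at least 10 in at least 4 libraries, which left 14312. Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3, with line (control, e135, e136) and sex as terms and a mean-variance trend. Deletion versus control is the mean of both lines minus control. The interaction of genotype and sex was taken from the 6 means of line by sex, with 2 libraries each. Adjusted p are Benjamini-Hochberg values over the tested genes, and a gene was called under 0.05. Pitx2 was also compared by exact two-sided permutation tests of the difference of mean log2 values.

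Lists of genes fixed in advance were tested by camera with a preset correlation of 0.01, with an estimated correlation, and by fry, for the 30 lists with at least 3 tested members. Fry called 4 lists in deletion versus control, 0 in e135, 8 in e136 and 1 between the lines. Its directional p tests whether the genes of a list move on balance one way, and compares no list with other genes. Of the mitochondrially encoded genes 0 of 15 are in the table, and of the lung markers 4 of 13 are in it and 0 passed the filter. Positions are from GENCODE M21 for GRCm38: 16371 names matched a symbol, 413 a synonym and 886 neither. The library label f1, f2, m1 or m2 was used as sex and replicate only.

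Genes were named by a rule. It took Pitx2 and its 4 neighbourhood list members of smallest p, counting Pitx2 where it ranked. For deletion versus control it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 50 and the same sign in both lines. It took 5 each way for e135, e136, their difference and sex, 3 each way for the interaction, and up to 4 members of each list. Unnamed gene models were passed over.

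The tests were tried on simulated libraries with the observed means and dispersions, in which 200 genes were changed by 1.5-fold, 2-fold or 4-fold. In deletion versus control 74.6%, 92.5% and 93.9% of these were called in the true direction, with 10 calls of unchanged genes. For the interaction the shares were 25.4%, 64.2% and 90.9%, with 11 such calls. The simulation assumes that libraries of one line and sex vary independently, and does not include differences between the 6 groups of line by sex beyond those planted.

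The alternatives set before the data were examined were log2(value + 0.5) and log2(value + 5), no filter and a minimum of 50, quantile normalization, TMM rescaling, no trend, array weights, no sex term, a replicate block, 1 deletion group, a fit of the compared groups alone, and leaving out each library. On the whole reads they were edgeR 4.0.16 with TMM or DESeq2 size factors and DESeq2 1.42.0. Chosen after seeing the data were leaving out the 3 libraries with the most Myl2, a score of 9 clock genes as a covariate, libraries of each sex alone, and camera with an estimated correlation as a count. Splits of the libraries numbered 35 where all could be run and 100 drawn at random otherwise.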

Results

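RNA was sequenced from the left atrium of 3-month-old FVB mice, an inbred laboratory strain, in 12 libraries. Control mice were compared with mice that lack Enh20k, an enhancer named for Pitx2, the transcription factor gene that sets left identity in the embryo. The deletion libraries carry the names e135 and e136, whose meaning is not given in the sources used here. Each of the 3 groups held 4 libraries, 2 from females (f1, f2) and 2 from males (m1, m2). Whole reads assigned to genes came to between 11935100 (control m1) and 28690100 (control f1) per library.

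The sample labels name the left ventricle and the extraction protocol names the left atrium. Myl7, the atrial myosin light chain, lay between 58866 (e136 m1) and 172972 (control f1) normalised reads. Myl2, its ventricular counterpart, lay between 10.6 (control f1) and 2327 (e136 f2). Irx4, a ventricular transcription factor, had 0 to 8 reads per library. Myl2 was highest in e136 f2, e135 f2 and e136 f1, the last 2 at 645 and 618, and no other library exceeded 96.1.

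The first question was whether Pitx2 itself, on chromosome 3 from 129199878 to 129219591 of GRCm38, changed. It measured 242 ± 43.1 (SD, n = 4) normalised reads in controls, 192 ± 34.2 in e135 and 230 ± 34.1 in e136. The difference between deletion and control was -0.20 on the log2 scale (SE 0.13, limma adjusted p = 0.424), with a 95% interval from -0.48 to 0.07. That interval spans 71.9% to 105% of the control level. An exact two-sided permutation test over all splits of the libraries gave p = 0.228. For e135 alone the difference was -0.34 (SE 0.14, limma adjusted p = 0.262, exact permutation p = 0.114 over 70 splits). For e136 it was -0.07 (SE 0.14, limma adjusted p = 0.818, exact permutation p = 0.686). The estimate was 0.08 (adjusted p = 0.660) in female libraries alone and -0.49 (adjusted p = 0.123) in male libraries alone. The test of that difference between the sexes gave -0.57 (SE 0.20, adjusted p = 0.102). Without control m1, which had the highest value, the estimate was -0.04.

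**Figure D1:**
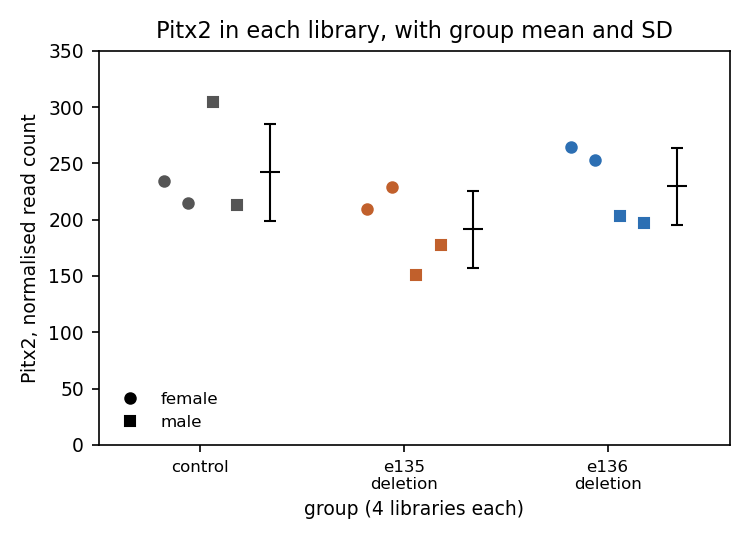
Normalised read count of Pitx2 (vertical axis) in the 12 libraries by group (horizontal axis). Circles are females, squares are males, and the bars give the mean and SD of 4 libraries; control m1 is highest at 304.9 and e135 m1 lowest at 151.2.

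Of 19 tested genes in the chromosome 3 neighbourhood of Pitx2, 0 passed the test, and 1 rose when adjusted over the list alone. That gene was Cfi, a complement regulator, at 42.3 ± 11.6 in controls, 67.1 ± 13.6 in e135 and 80.4 ± 26.5 in e136 (log2 difference 0.78, adjusted p = 0.0672 over all genes). Alpk1 differed by 0.36 (adjusted p = 0.123) and Enpep, the gene next to Pitx2, by 0.14 (adjusted p = 0.463).

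Adamts8, a secreted metalloprotease (chromosome 9, 30942562 to 30963838), rose from 1754 ± 302 in controls to 5732 ± 1629 in e135 and 5454 ± 1515 in e136 (log2 difference 1.64, SE 0.19, adjusted p = 0.00139). Ptprt, a receptor tyrosine phosphatase (chromosome 2, 161521990 to 162661147), rose from 13.9 ± 10.7 to 229 ± 106 and 43.5 ± 27.8. Ryr3, a calcium release channel of the sarcoplasmic reticulum, rose by 1.24 (SE 0.24), and Acta1, the skeletal muscle actin, by 2.70 (SE 0.63; call lost in 15 of 30 alternatives). Tnni1, the slow skeletal troponin I (chromosome 1, 135779434 to 135810989), went from 122 ± 27.0 to 15.6 ± 11.2 and 70.8 ± 34.1 (log2 difference -2.06, SE 0.27). Ucp3, a mitochondrial carrier (chromosome 7, 100472990 to 100486432), went from 278 ± 50.7 to 64.7 ± 24.0 and 157 ± 75.0 (log2 difference -1.53, SE 0.24).

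The ranking here covers only named genes that were called, with a mean of at least 50 and the same sign in both lines. Among the other genes with the largest rises were Ciart, a clock repressor (1.91), Mt2, a metal-binding protein (1.79), Shisa3 (1.48, call lost in 18 of 30 alternatives), Itih4 (1.28), the long noncoding RNA Dubr (1.21) and Bdh1, an enzyme of ketone body metabolism (1.18). Those with the largest falls were Tep1, a telomerase-associated protein (-2.08), Sfrp5, a secreted Wnt antagonist (-1.94), Fosb (-1.74), Snord104, a small nucleolar RNA (-1.69), Errfi1, an inhibitor of the EGF receptor (-1.45), Nr4a1 (-1.39), Egr1 (-1.38) and Adra1a, an adrenergic receptor (-1.35). Their adjusted p ranged from 0.000229 (Tep1) to 0.0454 (Sfrp5). Dubr owed its average mostly to e135, with 81.8 ± 8.0 in controls, 377 ± 85.4 in e135 and 98.2 ± 12.6 in e136. Tep1 was at 786 ± 96.5, 520 ± 224 and 69.9 ± 11.5.

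**Figure D2:**
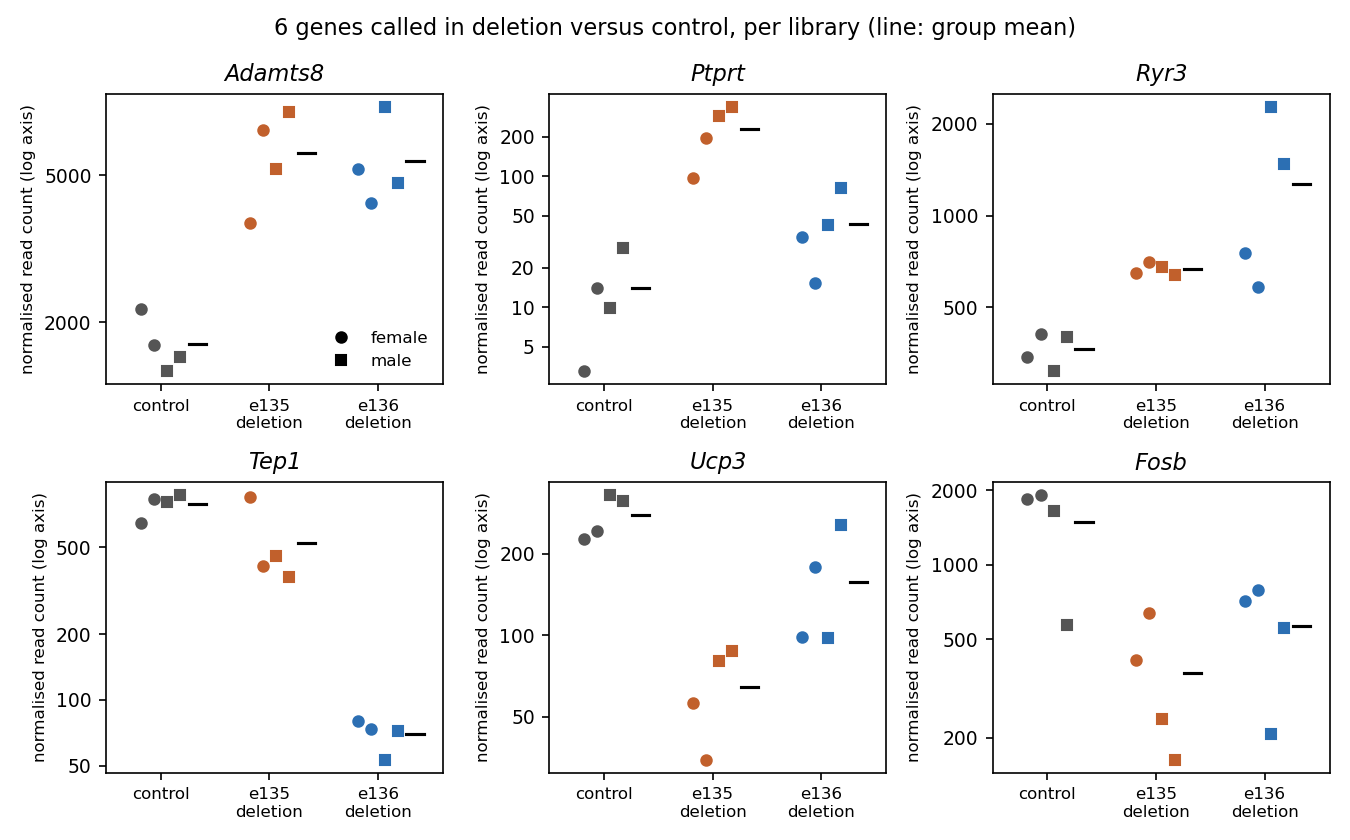
Normalised read counts (logarithmic vertical axes) of Adamts8, Ptprt, Ryr3, Tep1, Ucp3 and Fosb in the 12 libraries by group (horizontal axes); circles are females, squares are males and lines are group means. Every deletion library has more Adamts8 (3715 or more) than any control (2177 or less), while Tep1 is lowest in e136.

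Immediate early genes, which respond first to stimulation and include many transcription factors, fell as a group. Of 22 tested members 5 fell and 1 rose, or 15 fell and 1 rose when adjusted over the list alone (camera adjusted p = 2.36e-08). With an estimated correlation the adjusted p = 0.249. Fosb measured 1493 ± 626 in controls, 364 ± 212 in e135 and 568 ± 259 in e136. Egr1 measured 7652 ± 2790, 2230 ± 803 and 3845 ± 1150, and Nr4a1, Jun and Zfp36 also fell. The mean level of the list overlapped between groups, since control m2 lay at -0.47 and e135 f2 at -0.30 relative to the control mean.

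Markers of macrophages rose as a group, with 3 of 17 members called, or 6 when adjusted over the list alone (adjusted p = 1.96e-06; adjusted p = 0.266 with an estimated correlation). The 3 were the subunits of complement C1q, C1qa, C1qb and C1qc, by 0.37, 0.42 and 0.41, with the call of C1qa lost in 18 of 30 alternatives and that of C1qb in 15. Of 39 genes of the extracellular matrix and fibroblasts, 3 rose, or 9 when adjusted over the list alone (adjusted p = 1.10e-05; adjusted p = 0.527 with an estimated correlation). These were Cilp (0.95), Thbs4 (1.09) and Tgfb1 (0.28), the last 2 with calls lost in 16 of 30 alternatives each. The level of this list relative to the control mean was -0.10 in e135 m1 and 0.03 in e135 m2, within the control range of -0.14 to 0.17. In the other deletion libraries it ran from 0.26 to 0.66. The smooth muscle and pericyte list had a median difference of 0.28 with 0 of 14 members called, also 0 when adjusted over the list alone (adjusted p = 0.00231; adjusted p = 0.266 with an estimated correlation). Erythroid genes had a median of 0.60 with 0 of 5 called, or 4 when adjusted over the list alone (adjusted p = 0.00498; adjusted p = 0.550 with an estimated correlation). Relative to the control mean, the erythroid level ran from 0.40 to 1.37 in e135 and from -0.33 to 0.56 in e136. In the controls it ran from -0.65 to 0.31.

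Atrial cardiomyocyte markers fell as a group, with 1 of 14 called, or 2 when adjusted over the list alone (adjusted p = 0.000447; adjusted p = 0.451 with an estimated correlation). The called member was Myl7 (-0.54, SE 0.13, adjusted p = 0.0453), a call lost in 18 of 30 alternatives, all 4 omissions of a control library among them. Tbx5 was at -0.28 (adjusted p = 0.0996) and Kcnj3 at -0.32 (adjusted p = 0.175). The library e136 m1, which stood apart on the first principal component (46.2, next 26.9), had the lowest list level, at -0.65. Nuclear genes of oxidative phosphorylation had a median of -0.10 with 0 of 42 called, also 0 when adjusted over the list alone (adjusted p = 0.00231; adjusted p = 0.822 with an estimated correlation). This came from e136 (-0.22), since in e135 the median was 0.01, with 24 of 42 above 0 (adjusted p = 0.825). Of the left-right and right atrial genes 3 were tested, and 0 were called, or 3 when adjusted over the list alone (adjusted p = 0.00796; adjusted p = 0.285 with an estimated correlation). Bmp10, a growth factor of the right atrium, had 1 to 16 reads in each control and 16 to 1550 in each deletion library (adjusted p = 0.0619). Hamp, a peptide hormone gene of the same list, was at 158 ± 70.8 in controls, 318 ± 133 in e135 and 258 ± 144 in e136 (adjusted p = 0.281).

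**Figure D3:**
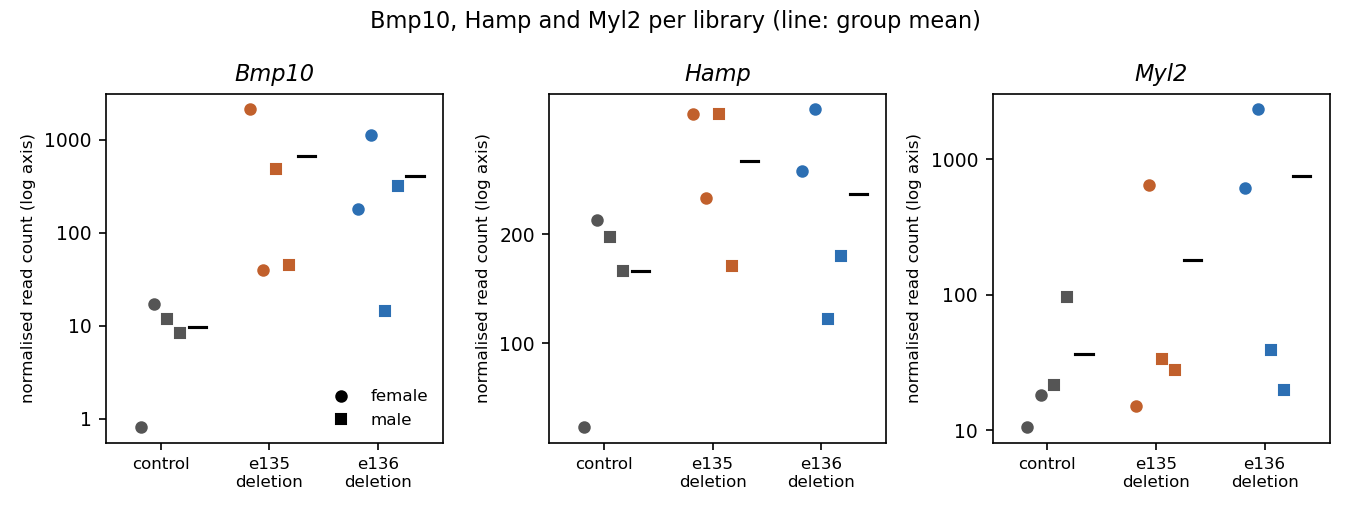
Normalised read counts (logarithmic vertical axes) of Bmp10, Hamp and Myl2 in the 12 libraries by group (horizontal axes); circles are females, squares are males and lines are group means. Bmp10 is at most 17.3 in the controls and reaches 2120 in e135 f1, while Myl2 is highest in e136 f2 at 2327.

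RNAs without a poly(A) tail fell as a group, with 3 of 9 called, or 4 when adjusted over the list alone (adjusted p = 0.000694; adjusted p = 0.451 with an estimated correlation). These were Rmrp (-0.96), Rny1 (-1.14) and Rny3 (-1.02), whose call was lost in 18 of 30 alternatives. The groups overlapped in the level of the list relative to the control mean. It was -0.05 in e135 m1, -0.07 in e135 m2 and -0.31 in e136 m2, within the control range of -0.39 to 0.42. In the other deletion libraries it ran from -0.80 to -0.49.

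**Figure D4:**
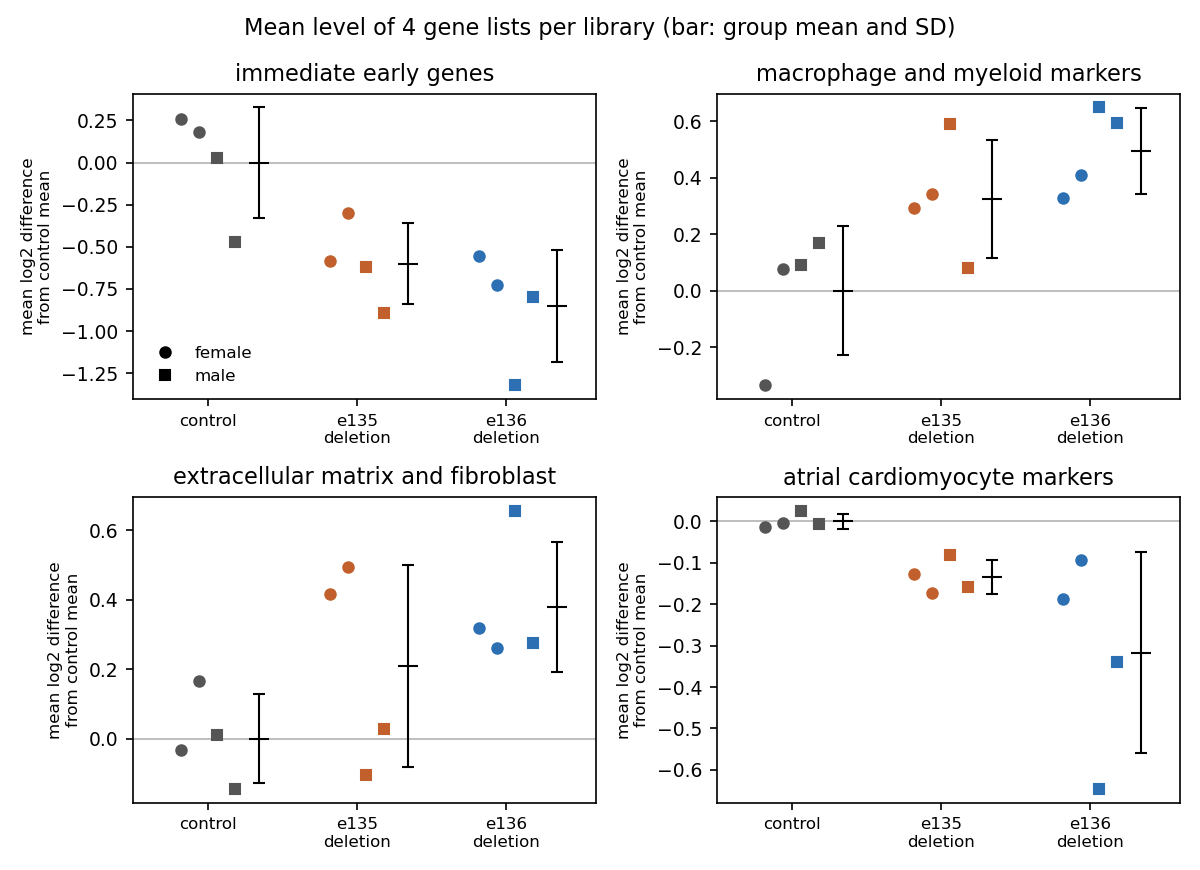
Mean log2 difference from the control mean (vertical axes) of 4 gene lists in the 12 libraries by group (horizontal axes); circles are females, squares are males and bars give the mean and SD of 4 libraries. Immediate early genes are lowest in e136 m1 (-1.32), and atrial cardiomyocyte markers lie below the control mean in all 8 deletion libraries (-0.65 to -0.08).

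The remaining 21 lists were not called by camera in deletion versus control. Their adjusted p were 0.559 for the Pitx2 neighbourhood, 0.707 for ventricular markers, 0.886 for sinoatrial node genes, 0.697 for ion channels, 0.308 for calcium handling and 0.308 for intercalated discs. They were 0.115 for the sarcomere, 0.229 for the antioxidant response, 0.629 for fatty acid oxidation, 0.446 for cardiac stress genes, 0.590 for endothelial markers and 0.697 for lymphocyte markers. They were 0.235 for mesothelial markers, 0.472 for adipocyte markers, 0.959 for Schwann cell and neuron markers, 0.423 for the interferon response and 0.115 for the circadian clock. They were 0.115 for heat shock, 0.618 for the cell cycle, 0.235 for atrial fibrillation loci and 0.311 for sex chromosome genes. Single members were called in some of these lists: Scn1b rose by 0.48 and Scn10a fell by 0.68 among sodium channel genes, Fhl2 fell by 0.71 among disc genes, and Vsnl1 fell by 1.12 among sinoatrial genes. Hmox1 rose by 0.87 and Ucp2 by 0.55 in the antioxidant list, Nr1d1 rose by 1.01 and Npas2 fell by 1.08 among clock genes, Tek fell by 0.33 among endothelial genes, and Igkc rose by 1.78 among lymphocyte genes (adjusted p = 0.0472). The call of Igkc was lost in 22 of 29 alternatives, and those of Vsnl1 and Ucp2 in 16 of 30 each.

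In all, 355 of 14312 tested genes differed between deletion and control by limma at an adjusted p under 0.05. Of these 199 were higher and 156 lower, and 70 differed at least 2-fold. The number of calls depended on single libraries: it was 73 without control m2, 129 without control f1, 179 without e135 f2, 190 without control m1, 216 without e136 m2, 219 without control f2 and 231 without e135 m2. With the 6 means of line by sex in the fit, the 2 control groups against the other 4 called 1186 genes, and 3 of the 14 other contrasts of 2 groups against 4 called at least as many.

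Each line was then compared with the controls on its own. In e135, Ptprt rose by 4.12 (SE 0.43), Scd4, a fatty acid desaturase, by 2.69 (SE 0.45; 104 ± 68.2 against 595 ± 244), Dubr by 2.17 (SE 0.17), Ciart by 2.00 and Mt2 by 1.98. Tnni1 fell (-3.21, SE 0.31), and lower were also Sfrp5 (-2.26), Ucp3 (-2.15), Fosb (-2.08) and Egr1 (-1.79). In e136, Acta1 rose by 4.13 (SE 0.73), Ciart by 1.82, Shisa3 by 1.75, Lgals3, a galectin of macrophages, by 1.68 and Adamts8 by 1.61 (SE 0.22). Tep1 fell by 3.48 (SE 0.21), Ogdhl, an enzyme of mitochondrial metabolism, by 2.66 (SE 0.27) and Atf3, a stress-induced transcription factor, by 2.33. In e136 the calls of Shisa3, Atf3, Ciart and Lgals3 were lost in 21, 20, 19 and 16 of 30 alternatives. The heat shock genes Hspa1a and Hspa1b fell by 4.09 and 3.75 in e136, but their near-identical sequences leave reads hard to assign between them.

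The e135 comparison called 353 genes (194 higher, 159 lower) and the e136 comparison 260 (108 higher, 152 lower). Both called 37 genes as higher, 37 as lower and 0 in opposite directions, but the shared controls alone favour such overlap. How much of it they give was not settled. Simulations of unchanged groups had 0 genes called in both lines, but such groups hold no true changes to share. Across tested genes, which are not independent replicates, the 2 sets of log2 differences correlated with r = 0.532. Since both use the same 4 controls, simulated unchanged groups gave r = 0.505 on average (highest 0.531). Their covariance was 0.0540, against 0.0179 in the simulations, and 0.0360 and 0.0355 when each line was compared with a different pair of controls. With those separate controls r was 0.301 and 0.298. Each pair held a control female and a control male, so whatever the control libraries have in common stays in both comparisons. The share of genes with the same sign in both lines was 65.6%, against 66.7% in the simulations (highest 67.6%), so it did not exceed what the shared controls give.

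By camera, 12 lists were called in e135 and 10 in e136, and 0 in either with an estimated correlation, while fry called 0 and 8. Erythroid genes in e135 had 2 of 5 members called as higher, or 4 when adjusted over the list alone (adjusted p = 0.00019; adjusted p = 0.484 with an estimated correlation). Nuclear oxidative phosphorylation genes in e136 had a median of -0.22 and 0 of 42 members called, also 0 when adjusted over the list alone (adjusted p = 3.19e-08; adjusted p = 0.631 with an estimated correlation). Relative to the control mean, the level of that list was -0.45 in e136 m1 and -0.20 in e136 f1. In e136 f2 and e136 m2 it was -0.09 and -0.08, within the control range of -0.14 to 0.18. The e136 count was 92 without control f2, 105 without e136 m1, 108 without control m2, 110 without control f1, 115 without e136 f1, 118 without e136 m2, 144 without control m1 and 172 without e135 f1. The e135 count was 146 without control m2, 156 without e135 m2, 172 without e135 f2, 195 without control f1 and 230 without control m1.

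The direct comparison of e135 with e136 found the lines apart in several of these genes. Ogdhl was higher in e135 (227 ± 116 against 15.1 ± 2.92, log2 difference 3.68, SE 0.27), as were Tep1 (2.81, SE 0.21), Scd4 (2.63) and Hspa1a and Hspa1b (4.19 and 4.03). Lower in e135 were Tnni1 (-2.30), Ucp3 (-1.24, call lost in 21 of 30 alternatives), Lipo2 (-1.22), Tnni2, the fast skeletal troponin I (-1.13), and Pdzd7 (-1.12, 36.5 ± 3.13 against 81.8 ± 18.7). Of 17 tested cell cycle genes 4 were higher in e135, or 8 when adjusted over the list alone (adjusted p = 6.53e-07; adjusted p = 0.681 with an estimated correlation). Nuclear oxidative phosphorylation genes had a median of 0.22 and 0 of 42 members called, also 0 when adjusted over the list alone (adjusted p = 5.34e-09; adjusted p = 0.681 with an estimated correlation). The levels of that list overlapped between the lines, at -0.11 in e135 f2 and -0.08 in e136 m2 relative to the control mean. limma called 187 genes, 116 higher and 71 lower in e135, and camera called 8 lists, against 0 with an estimated correlation and 1 by fry. The gene count was 56 without e135 m2, 69 without e135 m1, 71 without e136 m2, 88 without e136 m1 and 89 without e136 f1.

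The sexes were compared over all lines. Male libraries held Ddx3y (2262 ± 256, n = 6), Uty (881 ± 122), Eif2s3y (791 ± 61.3) and Kdm5d (527 ± 31.7), genes of the Y chromosome. In the 6 female libraries Uty, Eif2s3y and Kdm5d were at 0 and Ddx3y had 1 read, in control f1. Xist, the RNA that silences an X chromosome, measured 7119 ± 622 in females and 4.48 ± 2.91 in males, so every library carried the sex its label gives. C7, a complement component, was higher in males (4855 ± 917 against 565 ± 61.8, log2 difference 3.09, SE 0.11, adjusted p = 2.21e-09). Fbln7, a matrix protein, was lower in males (-1.82), as were Otud1 (-1.52), Myl3, a ventricular myosin light chain (-1.48), and Itih2 (-1.38). limma called 187 genes, 79 higher and 108 lower in males, and 115 without e135 f2, 118 without e136 f2 and 121 without e135 f1. Without the 3 libraries with the most Myl2, all female, it called 58, and neither Myl3 (-0.94, adjusted p = 0.372), Otud1 (-1.59, adjusted p = 0.0983) nor Itih2 (-1.05, adjusted p = 0.237) passed. That fit had fewer libraries and the 3 stayed lower in males, so these lost calls do not tell where the differences come from.

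Whether the deletion difference depended on sex was tested as an interaction. Arntl, a core activator of the circadian clock, averaged 445 in control females, 62.3 in control males and 30.1 to 127 in the 4 deletion groups of 2 libraries (interaction 4.01, SE 0.42, adjusted p = 0.00115). Angptl7, a secreted angiopoietin-like protein, averaged 54.1 in control females and 158 in control males, with 376 in e135 females, 235 in e136 females and 62.5 in e136 males (-3.44, SE 0.34). Sfrp5 (-2.50) and Smpdl3b (-2.48) had a lower deletion difference in males, and Hspa1b (3.36) and Hspa1a (2.71) a higher one. limma called 848 genes, 430 with a higher and 418 with a lower deletion difference in males. Each of the 6 means rested on 2 libraries, and the count was 70 without control m1, 75 without control f1, 311 without e135 f1, 404 without e136 f1, 444 without e136 f2, 543 without control f2 and 1552 without e136 m2.

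**Figure D5:**
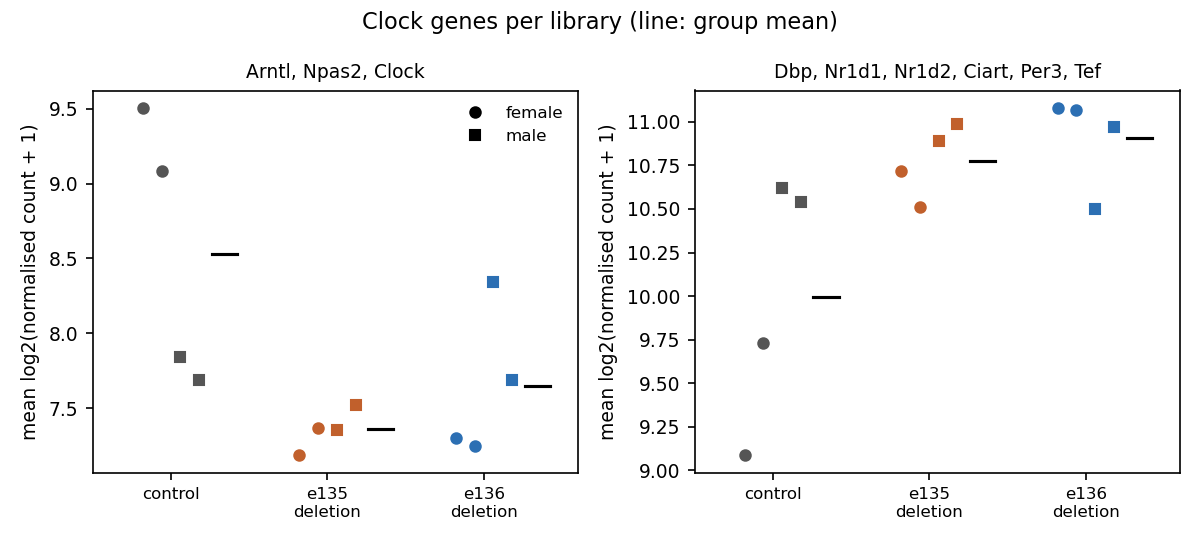
Mean log2(normalised count + 1) of Arntl, Npas2 and Clock (left, vertical axis) and of Dbp, Nr1d1, Nr1d2, Ciart, Per3 and Tef (right, vertical axis) in the 12 libraries by group (horizontal axes); circles are females, squares are males and lines are group means. The control females lie highest on the left (9.08 and 9.51) and lowest on the right (9.09 and 9.73).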

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

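The splits of the libraries and the count of contrasts for the interaction of genotype and sex were planned. No prediction was written for the contrasts of 2 groups against 4. The clock tests below were chosen only after the clock genes had been seen.

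Within groups of 4 libraries, 14 of 273 groups over 91 items held a library far from the other 3, measured as its gap to the nearest divided by the range of the group. Chance alone gives about 1 in 20 groups, or 13.65. The high libraries were control f2 for Mt2 (gap 0.861 of the range) and Lgals3 (0.855), control m2 for Lefty1 (0.867) and Tagln (0.976), e136 m1 for Shisa3 (0.948), e135 f2 for Atf3 (0.899), e135 m2 for C1qb (0.914), e136 f2 for Tbx5 (0.856) and e136 m2 for Rprl3 (0.836). The low libraries were control f1 for C1qa (0.883), e135 m1 and e136 f1 for Ucp2 (0.971 and 0.842), and e136 m1 for Nr4a1 (0.875) and Jun (0.939). Shisa3 stood at 267.8 in e136 m1 and at most 66.5 in the other e136 libraries, and Atf3 at 7874 in e135 f2 and at most 1275 in the other e135 libraries.

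Of the genes named for deletion versus control or as list members, 8 had a deletion difference that differed between e135 and e136, while 187 of all tested genes did. Genes named for other comparisons, such as Ogdhl and Scd4, are not in that count, though some of them differed too. It was larger in e135 by 2.454 for Ptprt, 1.907 for Dubr and 1.184 for Ctgf, a matrix-associated growth factor (adjusted p = 0.00169). The e135 difference minus that of e136 was 2.807 for Tep1, 4.188 for Hspa1a and 4.032 for Hspa1b, which were lower in e136. It was -2.302 for Tnni1 and -1.235 for Ucp3, which were lower in e135.

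The deletion difference in males minus that in females passed the test in 13 of the genes named. It was positive for Acta1 (2.264), Mt2 (1.757), Bdh1 (1.574), Scd4 (1.941), Hspa1a (2.707), Hspa1b (3.36), Arntl (4.008) and Cilp (0.9505). It was negative for Sfrp5 (-2.498), Angptl7 (-3.442), Smpdl3b (-2.476), Bhlhe41 (-0.7337) and Nr2f2 (-0.4952).

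The groups of line by sex differed in ways that the interaction does not single out. Of the 90 contrasts of the same form over the 6 groups, 42, the real one included, called at least as many genes as the 848 of genotype by sex, the highest other being 2240. A dependence of the deletion difference on sex therefore cannot be singled out from differences among these 6 groups in general, which may include litter or handling, neither given by the labels.

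For the 5 other comparisons, splits that reassigned single libraries reached the real count in a share under 0.05, the real split included. For deletion versus control 1 of 100 splits, the real one, called 355 genes, and the highest other called 4. For e135 it was 1 of 35 (353, highest other 2), for e136 1 of 35 (260, highest other 6) and for e135 against e136 1 of 35 (187, highest other 65, in the split by sex). For male versus female 2 of 100 splits called as many as 187. The other set control females and deletion males against the rest and called 378, which points to a structure of line by sex. These splits mix the 6 groups, so likeness of libraries within a group can keep their counts low, and they do not exclude such a structure. When whole groups were regrouped, 4 of 15 contrasts of 2 against 4, the real one included, called at least its 1186 genes. The highest other called 2266. By that count the difference of deletion from control cannot be singled out from differences among the 6 groups in general.

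The groups of line by sex also differed in clock genes, picked from the list of 19 after their values were seen. Arntl, Npas2 and Clock averaged 9.29 on the log2 scale in control females and 7.77 in control males, a difference of 1.527 against at most 0.653 between libraries of one line and sex, so the deletion cannot be the only cause. A first test, a correlation of these 3 genes with Dbp, Nr1d1, Nr1d2, Ciart, Per3 and Tef over all 12 libraries, passed its bound of -0.6, but the control females stand apart from the rest. Within the other 10 libraries r = -0.518 (permutation p = 0.119; rho = -0.539, permutation p = 0.116; adjusted p = 0.149 over 5 relations; -0.177 without e136 m1 and control m1), which leaves different clock phases undecided. A count added after that result, 9 of 9 of these genes differing between control females and control males in the direction of one phase shift, restates a pattern for which the genes were picked and decides nothing. Whether times of collection differed stays open, since they are not given in the sources used here, and a biological difference between the sexes in controls was not tested.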

How the results depend on the processing

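The clock covariate, the fits of each sex alone, the fit without the 3 libraries with the most Myl2 and the estimated correlation were chosen after seeing the data. The cause was not tested for any of the changes below. Fits of fewer libraries had smaller groups, and called more genes in some comparisons and fewer in others. Genes called in deletion versus control, 355 as reported, were 173 without the trend, 141 with no sex term, 141 with the 8 deletion libraries as one group, 155 with a replicate block, 717 by DESeq2, 2087 with the clock score as a covariate and 1000 in female libraries only. For e135 versus control (353) they were 220 without the trend, 220 with no sex term, 178 with the block, 669 by DESeq2, 145 without the 3 libraries with the most Myl2, 1345 with the clock score and 745 in females. For e136 versus control (260) they were 86, 87, 69, 741, 912, 2443 and 602 in the same order, 1077 in males and 130 with only the 2 groups compared in the fit. For e135 versus e136 (187) they were 98, 119, 69, 618, 929, 580 and 85, and 940 in males. For male versus female (187) they were 435 by DESeq2, 58 without the 3 libraries and 1032 with the clock score. For genotype by sex (848) the count was 195 without the trend. As far as the labels say, replicate numbers do not pair libraries of different lines, so the block has no stated basis in the design. None correlated best with its own number, but that check kept the line by sex differences. Every best match was of the other sex, so it cannot decide. With the line by sex means removed, r between libraries of the same number ran from -0.097 to 0.160.

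Leaving out 1 library at a time gave 73 to 399 calls for deletion versus control, 146 to 507 for e135 versus control, 92 to 288 for e136 versus control, 56 to 182 for e135 versus e136, 115 to 202 for male versus female and 70 to 1552 for genotype by sex. Where this left 1 library of a line and sex, it was assumed to vary like the other groups. Pitx2 in deletion versus control ran from -0.30 to -0.04 in these fits and was 0.083, the opposite direction, in female libraries only. It was -0.49 in male libraries only, -0.43 with the clock score, -0.33 without the 3 libraries with the most Myl2 and -0.11 with arrayWeights, with adjusted p from 0.0945 to 0.902 over 30 alternatives. Enpep in deletion versus control turned to -0.017 with the clock score as a covariate (adjusted p = 0.942). Gene lists called in deletion versus control, 9 as reported, were 4 with the clock score, 5 in males, 0 with an estimated correlation, and 9 to 12 on leaving out 1 library. The correlation of e135 and e136 was 0.301 and 0.298 with the controls split, and 0.444 to 0.581 on leaving out 1 library.

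Pitx2, which reversed in female libraries only, and uncalled genes named only as list members are left out of the next counts. Of 2666 alternative values of the other named genes, 2094 kept their direction and side of the threshold. Another 566 kept the direction and lost the call, 5 gained a call and 1 reversed. The call was the same in every alternative for 25 of 92 pairs of gene and comparison, among them Adamts8, Fhl2 and Nr1d1 in deletion versus control. Control m1, with 11935100 reads, limits the depth of the control group.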

Other observations

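The counts of the sexes separately and of small RNAs, and all tests of Bmp10 and of chromosome positions, were chosen only after seeing the data. The bound of the Myl2 test was reworded with the values already seen, and a test of chromosome segments carried by one line, written down earlier, was withdrawn once positions had been seen.

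Part of the difference between deletion and control libraries could be seen in each sex on its own, which does not tell its cause. In females alone 1000 genes were called and in males alone 521. Both called 35 genes as higher, against 11.85 for independent lists, and 35 as lower, against 6.695, while 18 were called in opposite directions. Among the shared genes, chosen here after their values were seen, were Adamts8 (1.31 in females, 1.98 in males), Ryr3 (0.83 and 1.64), Tep1 (-1.78 and -2.38), Tnni1 (-1.53 and -2.58), Ucp3 (-1.60 and -1.47), Fhl2 (-0.53 and -0.89) and the sodium channel gene Scn10a (-0.51 and -0.85). Fosb did not pass in males alone (-1.90, adjusted p = 0.0530), nor did Nr4a1 (-1.38, adjusted p = 0.107).

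Small RNAs were put together as a class after seeing the data, and no set test was run on them. Of 47 tested small nucleolar, small nuclear and other small RNAs, 10 fell, 0 rose and 37 did not pass in deletion versus control, and 38 had a negative difference, with a median of -0.43 (-0.32 in e135, -0.56 in e136). The called share was 21.3%, against 2.48% of all tested genes. Among the called ones were Snord49b (-2.15), Snord82 (-2.13), Snord49a (-1.95) and Snord83b (-1.78), and also Rny1 and Rny3 of the list of RNAs without a poly(A) tail. Relative to the control mean, the mean level of the class was -0.51 in control f2, 0.51 in control m2 and 0.01 in e135 m1, so the groups overlapped.

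Bmp10, a growth factor of the right atrium, had 1 to 16 reads in the controls and 1550 in e135 f1, 1406 in e136 f2, 488 in e135 m1 and 380 in e136 m2. Ventricular tissue is argued against, since 2 of the 4 libraries with the most Bmp10 had less Myl2 than the median library. A lower Pitx2 level in the libraries with more Bmp10 stays open: with line and sex removed r = -0.00214 (95% interval -0.665 to 0.663; permutation p = 0.995; rho = -0.0559, permutation p = 0.870; 0.114 without e136 m1 and e135 f2), but the interval takes in the bound of -0.6 and the removal of line also takes out the difference to be explained. With line and sex removed, r between Bmp10 and Hamp was 0.8385 (0.839 without e136 m1 and e135 f2), but Hamp, a gene of the list fixed in advance, was tested after its values had been seen to follow Bmp10, and 58 of the other tested genes had an r at least as high. This decides nothing, so right atrial tissue in some libraries and a deletion that raises both genes cannot be told apart.

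Called genes were also examined for positions close together, after some of the largest e136 falls had been seen on chromosome 14. The densest 5 Mb window held 7 called genes in e136, 8 in e135 and 8 in deletion versus control. Random draws of as many tested genes reached those counts, in a window anywhere in the genome, in a share of 0.2284, 0.3305 and 0.3299. The largest counts alone therefore did not exceed those of random draws. The deletion window lay on chromosome 4, from Col16a1 to Oprd1. Its 8 genes were among 18 tested there, and 1 of them also differed between e135 and e136. The scan scores only the largest count, so it does not test the share of called genes within a window. The 8 of 18 on chromosome 4 stand against 2.48% called among all tested genes in deletion versus control. Whether that window exceeds chance was not tested and stays open. In the e136 window a share of 0.1429 of the called genes also differed between e135 and e136, and 4 of the 7 were called in e135. In the e135 window, where the share and the use of its interval were added with the value already seen, it was 0.625 (5 of 8), and 0 were called in e136. So few genes, from windows picked for their calls, leave a response shared by both lines undecided. Between e135 and e136 the densest window held 8 called genes of 60 tested on chromosome 1, from Ikbke to Tnni1, a count reached in a share of 0.0081 of draws (adjusted p = 0.0486 over the 6 comparisons scanned). The scan of e135 against e136 was singled out after all 6 had been run, so it is a hypothesis that a chromosome segment may differ between the lines. No variant data were used here, and no other explanation was tested.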
